A study of Rattus norvegicus with 6 samples.

How the data were processed

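Whole-lung gene expression was measured in male Wistar rats after whole-body inhalation exposure for 4 weeks, per the labels. The rats breathed clean air (control), C60 fullerene, a cage-shaped carbon molecule given as an aerosol of fine particles, or ultrafine nickel oxide (NiO), which the labels name as a positive control. Lungs were taken 3 or 33 days after the end of exposure, called 3 days and 1 month here. Per the labels, the lungs were perfused with saline and RNA of the right lung was labelled with Cy3 and hybridised to 1-colour whole rat genome oligonucleotide arrays, with 4 array positions on each slide. The 6 labelled samples were the 6 groups, and each group came with 3 or 4 scanner files, 1 per array position, so that 23 arrays were read.

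Per the file headers, Feature Extraction version 9.5.3.1 with protocol GE1-v5_95_Feb07 turned each scan into spot intensity values, and the deposited processed intensity already had background subtracted and a spatial trend removed. The grid of the headers names the rat build rn4, and no coordinates were used. The value table deposited by the authors held a linear ratio per probe and group, and its making is not given in the sources used here. It was rebuilt from the scanner files: each array divided by its own median, the geometric mean of a group's arrays taken, and the result divided by the per-probe median of the control arrays of the same time. With any constant offset of a column taken out, this matched the deposited ratio columns to within a median of 0.000838 log2 units or less in each group. The match was read over the 20357 probes whose mean signal lay above the array median. The medians of these columns were 1.006 for control, 1.038 for C60 and 0.986 for NiO at 3 days, and 0.997, 1.125 and 1.133 in the same order at 1 month. The match settled scale and direction of these columns (particle over control) but not their centring, and the table entered no test.

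The label of the C60 group at 3 days gave n = 2, while 4 arrays came with it. Arrays 1 and 2 alone matched the deposited C60 column (median absolute log2 difference 0.00082), and all 4 arrays together did not (0.109). By the rule fixed for this case, arrays 1 and 2 were used, and all 4 arrays were an alternative. The comparisons therefore rest on 21 arrays: 3 control, 2 C60 and 4 NiO at 3 days, and 4 of each at 1 month. That 1 array stands for 1 rat was read from the n of the labels and the number of right lungs in the design text. The p-values measure the spread between these arrays. Each of the 6 slides held 1 group, so slide and group cannot be told apart within a time. All 3-day arrays were scanned on 1 day and all 1-month arrays on another, so scan day and time cannot be told apart either.

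Control spots were left out, as were spots with an outlier mark of the scanner software unless every spot of a probe had one, spots of 1 probe were averaged, and saturated spots were kept. The value used was log2 of the processed signal minus the array's 75th percentile of it, over 41012 probes. A probe was kept where it was well above background on every used array of at least 1 group, which left 28677 probes. Names came from the accession of the probe through a gene table of assembly GRCr8 (10768 probes by the main accession and 89 by another one), from a current symbol (5044) or an older symbol (3380), and otherwise from the file itself (2772). The remaining 18959 probes had no gene name and were tested under their probe identifier. The names covered 22053 probes and 17483 distinct symbols. For a gene with more than 1 kept probe (3022 genes) the probe with the highest mean signal was used. This gave 24984 features, called genes below, of which 13539 had a symbol and 11445 did not.

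Differences were tested with limma (lmFit and eBayes, 15 residual degrees of freedom, prior degrees of freedom 2.31) in 1 fit over all 6 groups, which share 1 estimate of the spread. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Changes of at least 1 log2 unit were also counted. The comparisons were each particle against control, NiO against C60, the difference of each particle's effect between the times, and control against control between the times. A further fit took the slide mean as the unit, with 2 residual degrees of freedom. Log2 folds are given with their standard error (SE). A probe not well above background on any array of a group has only a bound there, given as "at least N-fold": the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own value and the lowest value among probes well above background. Differences between times with such a group are given as bounds ("or higher", "or lower") computed in the same way. No size is given where the dim group lies on the side that leaves the difference unbounded. Where only some arrays of a group were well above background, their number is given in comparisons of 2 groups.

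Gene lists, 33 in all, covered lung responses, lung and blood cell types, handling of the tissue and neighbouring tissue. They were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of members passing limma are given over all genes and adjusted over the list alone. The largest changes named are the 12 highest and 8 lowest log2 folds among called genes with a symbol (5 and 5 for NiO against C60 and for the differences between times). At least 1 of the groups compared had to be well above background on every array. In comparisons of 2 groups, no array of 1 group was allowed to overlap those of the other. Of the genes this rule names, 1 is not reported here. Groups, array use, tests, lists, this naming rule and the alternatives below were fixed before the data were examined. Which lists have members named was chosen after the camera results were seen, and for each the members with the largest called log2 folds were eligible.

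The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter (36442 features), a filter on every array (18959 features), eBayes with a trend, array weights, a fit of the compared groups only, the array position as a replicate block, all 4 C60 arrays, every probe tested on its own, and leaving out each array in turn. Comparisons on the same controls were set beside 20 simulations of unchanged groups. On simulated data of 24984 genes, changes of 1 and 2 log2 units were recovered for 49 and 86 percent of genes in the C60 comparison at 3 days, 64 and 89 percent in the NiO comparison at 3 days, 56 and 92 percent in the C60 comparison at 1 month and 62 and 87 percent in the NiO comparison at 1 month. The fit on slide means recovered 95.5 percent of simulated changes of 3 log2 units in NiO over both times. That share does not carry over to the data, where this fit did not call Tac1 at a log2 fold of -5.83. A list shift of 0.5 log2 units simulated in the NiO comparison at 3 days was recovered, with 0 of the other 32 lists called by camera. The share of spots well above background was between 57.4 and 78.3 percent per array, and the number of arrays limits the precision. As a check on the labels, 2 Y-linked probes were well above background on all 21 arrays.

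Software was R 4.3.3 with limma 3.58.1 and data.table version 1.17.8, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.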

Results

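Gene expression was measured in right lungs of male rats that had inhaled clean air, C60 fullerene or ultrafine nickel oxide (NiO) for 4 weeks. NiO served as the positive control of the study, so that the C60 values could be read beside those of a particle chosen for its effect. Arrays of 3 control, 2 C60 and 4 NiO lungs were compared at 3 days after exposure, and of 4 lungs per group at 1 month. Between 57.4 and 78.3 percent of spots were well above background on an array.

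Arrays of a group were alike to different degrees. Pearson correlations across genes within a group ranged from 0.989 to 0.991 for control and 0.946 to 0.987 for NiO at 3 days, and were 0.985 for the C60 pair. At 1 month they ranged from 0.962 to 0.990 for control, 0.989 to 0.992 for C60 and 0.990 to 0.996 for NiO. Genes are not independent replicates, so these values describe the arrays only. On the first principal component (32 percent of variance) NiO arrays 2 and 3 of the 3-day slide lay at -107.93 and -112.79, while array 1 of that slide lay at -0.66, among the 3-day controls. Negative control spots gave a net signal of 142.69 on C60 array 1 and 64.4 on C60 array 2 at 3 days, against 24.3 to 40.8 on the other arrays. The share of spots well above background was highest on control arrays 3 and 4 at 1 month, at 78.3 and 77.1 percent among the arrays compared.

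At 3 days after NiO exposure the lungs showed a strong rise of genes of activated macrophages and of chemokines. Mmp12, the macrophage elastase, rose most, by a log2 fold of 6.41 (SE 0.61, n = 4 NiO and 3 control arrays; adjusted p = 2.83e-06). Cd177, a neutrophil surface protein, rose by 4.46 (SE 0.47; adjusted p = 8.69e-06) and Atp6v0d2, a subunit of the vacuolar proton pump, by 3.91. The anion exchanger gene Slc26a4 rose by 3.90 and Trem2, a lipid-sensing receptor of macrophages, by 3.55 (SE 0.34; adjusted p = 3.46e-06). The matrix metalloproteinase gene Mmp7 was at least 13.8-fold higher and Itih1, encoding a hyaluronan-binding serum protein, at least 9.29-fold higher than in control lungs, where neither was well above background on any array. Sdcbp2 and Slc17a1 were at least 4.48-fold and 3.82-fold higher in the same sense. Rnase9 (log2 fold 5.35, and 6.31 without control array 2) and Dmkn (3.46) were well above background on 1 of the 3 control arrays, and Spmip8 rose by 3.54. The largest fall was that of Tac1, the precursor of the neuropeptide substance P, which was at least 15.5-fold lower (log2 fold -6.05, SE 0.34; adjusted p = 7.22e-09) and not well above background on any NiO array. Dsg2, a desmosomal cadherin, fell by 3.59 on the log2 scale, Serpinb10 by 3.18 and Ctxn1 by 3.14 (3 of 4 NiO arrays well above background). Ntm fell by 3.60 (2 of 4) and Spry4, an inhibitor of receptor tyrosine kinase signalling, by 3.54 (1 of 4). Osbp2 and Hcrtr1 were at least 4.3-fold and 2.53-fold lower, and Hcrtr1 was not called with normexp background correction (adjusted p = 0.0804). By the naming rule, no array of 1 group overlapped those of the other for any of these 20 genes. Each stayed below an adjusted p of 0.05 whichever array was left out. For Dsg2 the control slide at 3 days stood apart: its mean was 0.11, against means between -4.90 and -3.48 in the other 5 groups, C60 and the 1-month controls included. It also lay at least 1 log2 unit above all other slides for Ctxn1, Ntm, Spry4, Osbp2 and Hcrtr1 and below them for Slc17a1 and Spmip8.

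**Figure D1:**
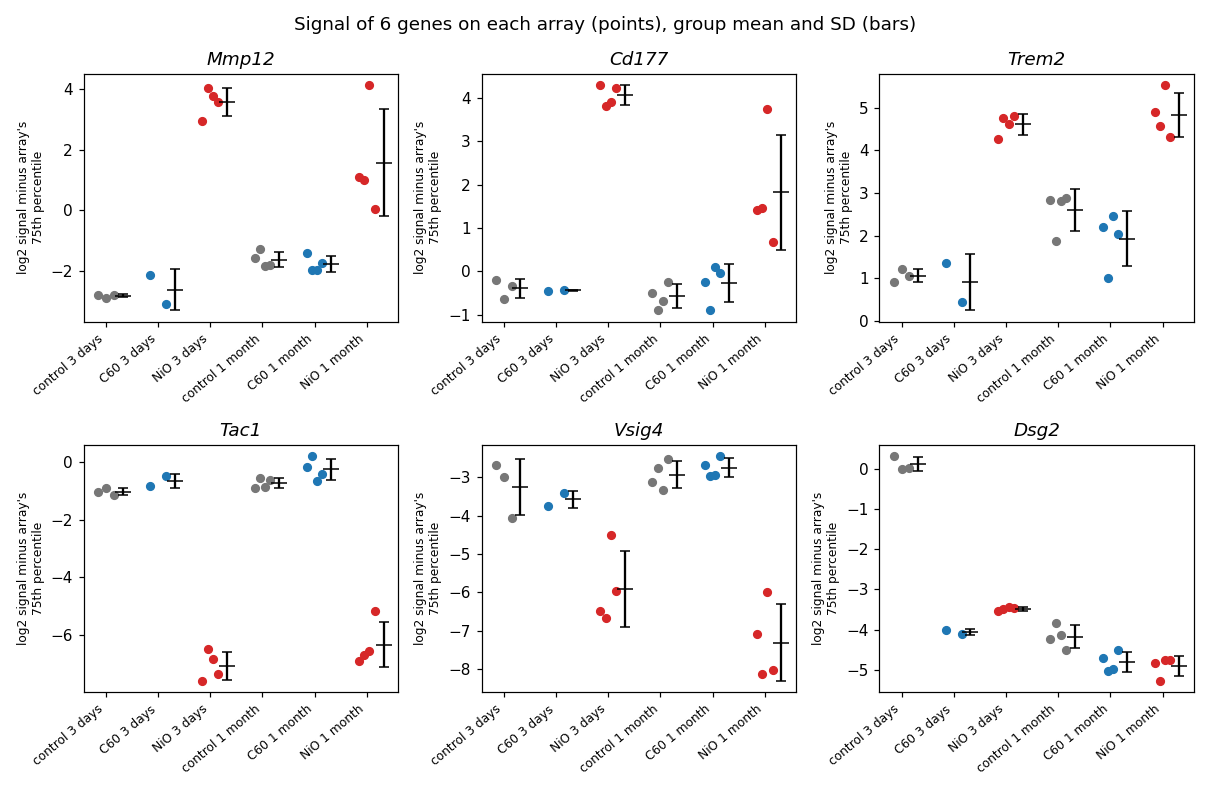
Log2 signal relative to each array's 75th percentile for Mmp12, Cd177, Trem2, Tac1, Vsig4 and Dsg2 in the 6 groups, with 1 point per array and bars for the mean and SD. Mmp12 averaged 3.58 in NiO lungs at 3 days against -2.84 in controls, Tac1 averaged -7.08 against -1.03, and Dsg2 was high only in the 3-day controls (mean 0.11).

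Of the gene groups, macrophage activation and lysosome genes rose most often after NiO at 3 days: 18 of 30 measured members rose and 1 fell (22 and 2 adjusted over the list alone), with a median log2 fold of 0.87. Chemokine and cytokine genes rose for 16 of 33 and fell for 3 (17 and 3 adjusted over the list alone), among them the neutrophil attractants Cxcl2 (3.32, SE 0.35; adjusted p = 8.61e-06) and Cxcl1 (2.80) and the monocyte attractant Ccl7 (2.99). Cell cycle genes rose for 15 of 30 members and fell for 1 (17 and 1 adjusted over the list alone), including Cks2 (1.38), the mitotic kinase gene Ttk (1.11) and the DNA topoisomerase gene Top2a (1.07). Genes of sterol and fatty acid synthesis rose for 10 of 25 (11 adjusted over the list alone), such as Fdft1 (1.11), Hmgcs1 (1.08) and Insig1 (1.07). In the complement list 9 of 23 rose and 1 fell (12 and 1 adjusted over the list alone), with C3 at 1.86, C4bpa at 1.79 and C4bpb at 1.71. Endothelial markers went the other way: 11 of 25 fell (14 adjusted over the list alone), for example Tie1, a receptor of endothelial cells, by 1.09 (SE 0.28; adjusted p = 0.0126). Camera called these shifts at adjusted p = 3.68e-10 for macrophage activation, 5.44e-06 for chemokines and 8.06e-06 for cell cycle, and at 2.13e-05 for sterol synthesis, 0.00129 for complement and 5.24e-06 for endothelial markers. None of these calls held with an estimated correlation: in the same order adjusted p = 0.165, 0.177, 0.232, 0.262, 0.274 and 0.165 with an estimated correlation.

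The Nrf2 and antioxidant list, targets of the oxidative stress regulator Nrf2, rose for 13 of 31 members and fell for 3 (15 and 5 adjusted over the list alone), led by the aldo-keto reductase gene Akr1b8 (1.74), the haem oxygenase gene Hmox1 (1.49, SE 0.13; adjusted p = 1.44e-06) and the mitochondrial superoxide dismutase gene Sod2 (1.12). Its camera adjusted p was 0.0238, but 0.0533 without NiO array 4, 0.0805 with normexp background correction, and adjusted p = 0.343 with an estimated correlation. Lists of the unfolded protein response (6 of 18 up) and of hypoxia targets (9 of 23 up, 1 down) shifted up at camera adjusted p = 0.00565 and 0.00745, and ciliated cell markers (4 of 22 down) shifted down at 0.00745, with adjusted p = 0.349, 0.165 and 0.274 with an estimated correlation. Adjusted over the list alone, 7 genes of the unfolded protein response rose, 10 hypoxia targets rose and 2 fell, and 6 ciliated cell markers fell. Another 6 lists passed with all arrays and lost the call without 1 array. They were metallothionein and metal handling (2 of 12 up; 0.0281, but 0.107 without NiO array 1 and 0.0527 without NiO array 4), acute phase genes (5 of 16 up; 0.0386, but 0.0619 without control array 3, 0.0741 without NiO array 1 and 0.0977 without NiO array 4) and xenobiotic metabolism (4 of 17 down; 0.0218, but 0.0599 without NiO array 1). The others were alveolar type I cell markers (4 of 17 down, 1 up; 0.0167, but 0.0599 without NiO array 1), smooth muscle markers (3 of 15 down; 0.026, but 0.0619 without control array 3) and red blood cell markers (2 of 13 down; 0.041, but 0.143 without control array 2, 0.0526 without NiO array 1, 0.0717 without NiO array 3 and 0.098 without NiO array 4). For these 6, adjusted p = 0.165, 0.343, 0.268, 0.349, 0.274 and 0.533 with an estimated correlation.

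Over all genes, limma called 4790 of 24984 in NiO against control at 3 days, 2658 higher and 2132 lower, of which 1311 and 448 by at least 1 log2 unit. Quantile normalization called 2231 higher and 2644 lower, a share of 45.8 percent higher against 55.5 percent. The count rested on single arrays: it was 2265, 2964 and 2647 without control array 1, 2 or 3, and 9606, 2696 and 2602 without NiO array 1, 2 or 3. Without NiO arrays 2 and 3 together, a choice made after seeing the data, 1638 genes were called. A fit of the compared groups only called 826. A regrouping that put NiO array 1 with the controls called 9923 genes.

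At 1 month after NiO exposure several macrophage genes were still higher than in control lungs, while Vsig4 was lower. Mmp12 was higher by a log2 fold of 3.20 (SE 0.56, n = 4 and 4; adjusted p = 0.00109), Cd177 by 2.40, Atp6v0d2 by 2.32 and Trem2 by 2.23 (SE 0.32; adjusted p = 0.00025). Slc26a4 was higher by 2.12, Itih1 by 2.01 and Dmkn by 1.90. Retnla, a secreted protein of alternatively activated macrophages, was higher by 2.85 and Lcn2, an iron-scavenging acute phase protein, by 2.21. The homeobox gene Meis3 was higher by 2.40 and Myo7a by 1.91. Among the NiO arrays, array 3 read above the other 3 for Slc26a4, Itih1, Lcn2, C3 and Hmox1. Without it Mmp12 was higher by 2.35 (adjusted p = 0.000196), Cd177 by 1.76 and Dmkn by 1.27, and without control array 2 Retnla was higher by 2.23 (adjusted p = 0.0221). Among the controls array 2 read below the other 3 for Trem2 and Myo7a. Zbtb16 was higher by 2.29 (adjusted p = 0.0214), a call lost without control array 2 (0.0795), NiO array 1 (0.0517) or NiO array 2 (0.0749), and its 2 probes gave 0.52 and 2.29. Tac1 was again lowest (-5.61, SE 0.31; adjusted p = 2.84e-08), well above background on 1 of 4 NiO arrays. Vsig4, a complement receptor of resident macrophages, was at least 7.39-fold lower and not well above background on any NiO array (adjusted p = 3.01e-05). Krt73, the olfactory receptor gene Or13a25 and the sperm gene Smcp were at least 13, 5.49 and 7.26-fold lower in the same sense. For Krt73 and Or13a25 these bounds were 8.06 and 3.48-fold without control array 2 and 21.7 and 8.74-fold without control array 3. Oit3 and Klk1c10 fell by 3.69 and 3.69 on the log2 scale (3.08 and 2.96 without control array 2, 4.34 and 4.45 without control array 3). For Krt73, Or13a25 and Smcp the mean of the 1-month controls lay at least 1 log2 unit above those of all other slides.

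In the 1-month NiO comparison the median log2 fold of all genes was -0.14, and 0.02 with quantile normalization, a shift of 0.15. Medians of lists are therefore given relative to all genes here. Macrophage activation and lysosome genes were higher for 17 of 30 members and lower for 1 (21 and 2 adjusted over the list alone; relative median 0.84). Genes of MHC class II antigen presentation were higher for 7 of 13 (7 adjusted over the list alone; relative median 0.61), with RT1-Db1 at 0.78 (SE 0.15; adjusted p = 0.00199) and RT1-DMa at 0.77. Complement genes were higher for 8 of 23 (8 adjusted over the list alone; relative median 0.41), including C2 (1.29), C4bpa (1.10) and C3 (0.90). Markers of alveolar type II cells, which make surfactant, were higher for 8 of 20 and lower for 1 (8 and 1 adjusted over the list alone; relative median 0.33), among them Cebpa (1.61), Muc1 (1.12) and the surfactant lipid enzyme gene Lpcat1 (0.94). Hypoxia targets were higher for 8 of 23 (8 adjusted over the list alone; relative median 0.43) and markers of macrophages and monocytes for 9 of 23 (9 adjusted over the list alone; relative median 0.46). Cell cycle genes were higher for 9 of 30, with 1 lower (11 and 1 adjusted over the list alone; relative median 0.38). Camera gave adjusted p = 2.79e-10 for macrophage activation, 9.15e-05 for MHC class II, 6.53e-05 for complement and 0.00145 for alveolar type II markers. The first 3 had adjusted p = 0.145, 0.221 and 0.221 with an estimated correlation, while the alveolar type II call held (adjusted p = 0.0461 with an estimated correlation). Camera gave 0.000966 for hypoxia targets, 0.00133 for macrophage and monocyte markers and 0.000235 for cell cycle. The hypoxia call held (adjusted p = 0.0461 with an estimated correlation), the other 2 had adjusted p = 0.221 and 0.299 with an estimated correlation. Against C60 at 1 month, limma called no alveolar type II marker (largest Lpcat1, 0.75, adjusted p = 0.108). It called no hypoxia target either (Hk2 0.80, 0.0845, and Pfkfb3 lower, 0.364). List means of alveolar type II markers were -0.24 to -0.18 on the 1-month controls and 0.06 to 0.13 on the 3-day controls. For hypoxia targets they were -0.24 to -0.14 and 0.01 to 0.06. NiO array 3 stood highest on several of these lists: its list mean was 1.04 for macrophage activation against 0.26 to 0.46 on the other 3, 0.50 for complement against 0.08 to 0.15, 0.44 for cell cycle against 0.11 to 0.22 and 0.40 for macrophage and monocyte markers against 0.02 to 0.15. Without this array these 4 lists had camera adjusted p = 1.56e-09, 0.000343, 0.00244 and 0.00467.

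In the Nrf2 and antioxidant list 8 of 31 were higher and 2 lower (9 and 2 adjusted over the list alone). Akr1b8 (1.47) and Hmox1 (1.32) were higher, and Gclm, which encodes a subunit of the enzyme that starts glutathione synthesis, was lower (-2.04, well above background on 2 of 4 NiO arrays). Gclm was at least 3.61-fold lower in C60 lungs as well, not well above background on any C60 array, and the 1-month control mean stood above those of the other 5 slides. For Cebpa the 1-month control mean lay at least 1 log2 unit below those of all other slides. Camera gave adjusted p = 0.00614 for this list, 0.0802 with quantile normalization and adjusted p = 0.299 with an estimated correlation. Genes of sterol synthesis (7 of 25 higher, 1 lower; 0.0099) also shifted up, with adjusted p = 0.487 with an estimated correlation and 0.0639 under a filter on every array. Acute phase genes (6 of 16 higher, 1 lower; 0.0231, but 0.0577 without NiO array 3), unfolded protein response genes (3 of 18 higher, 1 lower; 0.0231, but 0.0531 without control array 3) and clock genes (2 of 14 higher; 0.0349, but 0.0526 and 0.0634 without control array 2 or 3 and 0.073 without NiO array 4) shifted up with all arrays. These lists had adjusted p = 0.326, 0.508 and 0.299 with an estimated correlation, and 0.167, 0.139 and 0.0715 with quantile normalization. Over all genes limma called 7754, with 2798 higher and 4956 lower, of which 294 and 2191 by at least 1 log2 unit. Quantile normalization called 3750 higher and 3021 lower, 55.4 percent higher against 36.1 percent, and 778 and 1064 by at least 1 log2 unit.

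At 3 days after C60 exposure the lungs showed no rise of the macrophage activation or chemokine lists. Limma called 0 of 30 macrophage activation genes (1 higher and 1 lower at an unadjusted p under 0.05) and 0 of 33 chemokine genes (3 higher and 6 lower). The counts adjusted over the list alone were the same, and camera gave adjusted p = 0.986 and 0.99 for these lists. The largest changes were in other genes. Celsr1, a cadherin-like adhesion receptor, rose by a log2 fold of 2.89 (SE 0.20, n = 2 C60 and 3 control arrays; adjusted p = 1.12e-07), although its other probe gave -0.28. Acot1, a fatty acyl-CoA thioesterase, rose by 2.34, Cldn9, a tight junction claudin, by 2.09, and the olfactory receptor genes Or5w22 and Or14a258 by 2.27 and 2.08. F2r, the thrombin receptor gene, was at least 3.1-fold higher, Or9s14 and Olr193 at least 3.11-fold and Mgat5b at least 2.24-fold, none of them well above background on a control array. Another 3 calls in the 12 largest rises were lost without 1 array: Rpl29-ps23 (2.37; 2.97 without control array 3; 1.59 with adjusted p = 0.0807 without control array 1, 0.124 without C60 array 1 and 0.141 without C60 array 2), Rtn4rl1 (2.34; 0.0555 without C60 array 2) and Or12e9 (at least 4.21-fold; between 0.076 and 0.201 without any 1 of the 5 arrays). Dsg2 fell by 4.17 on the log2 scale (SE 0.19; adjusted p = 5.38e-10), and Ntm was at least 8.88-fold lower, Spry4 at least 5.82-fold, Mlnr at least 2.65-fold and Rnf151 at least 2.01-fold. Ctxn1 and F2rl3 were lower by -2.99 and -2.94 with 1 of 2 C60 arrays well above background. With normexp background correction Olr193, Mgat5b, Rtn4rl1, Or12e9 and Rnf151 were not called (adjusted p = 0.0932, 0.0614, 0.0578, 0.332 and 0.197).

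Camera called 2 lists in C60 against control at 3 days. B and plasma cell markers shifted up, with 1 of 15 higher (4 adjusted over the list alone; median 0.63; camera adjusted p = 0.000634, and adjusted p = 0.784 with an estimated correlation). Prdm1, a transcription factor of plasma cells, was at least 2.54-fold higher, with adjusted p = 0.0605 without C60 array 2. Markers of heart muscle, whose tissue adjoins the lung and its large veins, shifted down, with 2 of 18 lower (11 adjusted over the list alone; median -0.68; camera adjusted p = 6.95e-05, and adjusted p = 0.784 with an estimated correlation). The atrial peptide gene Nppa was lower by -4.23 (SE 1.19; 1 of 2 C60 arrays well above background). Without control array 1 it was lower by -5.05 and without C60 array 1 by -5.87. Without control array 2 it was -3.20 (adjusted p = 0.179), without C60 array 2 -2.58 (0.446), and without control array 3 the adjusted p was 0.0834. Csrp3 was lower by -1.03, with 0.0846, 0.143 and 0.395 without control array 2, control array 3 and C60 array 2. With normexp background correction these genes had adjusted p = 0.0718 and 0.0922. The heart muscle call was lost without C60 array 2 (adjusted p = 0.105), the B cell call with all 4 C60 arrays (0.0678) or with these averaged in pairs (0.0742). Over all genes limma called 1257, with 706 higher and 551 lower, of which 403 and 252 by at least 1 log2 unit. The count was 804 without control array 1, 761 without C60 array 1 and 747 without C60 array 2, and 3025 with all 4 C60 arrays. Among the 655 genes called with a fold of 2 or more, the control mean lay beyond the means of the other 5 slides for 84.9 percent and the C60 mean for 35.7 percent. Of the 20 largest changes named, 17 had a control mean at least 1 log2 unit beyond all other slides, the exceptions being F2r, Acot1 and Nppa.

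At 1 month after C60 exposure called falls of at least 1 log2 unit outnumbered rises, while over all calls the majority turned from falls to rises with quantile normalization. Rises included the clock gene Per3 (log2 fold 1.71, SE 0.44, n = 4 and 4; adjusted p = 0.0145; its other probe gave 1.29), the immediate early transcription factor gene Fos (1.62, SE 0.39; adjusted p = 0.0105) and Ube2o, a ubiquitin-conjugating enzyme gene (1.26; adjusted p = 0.00922). These 3 of the 12 largest rises stayed called whichever array was left out. The clock repressor gene Nr1d1 was higher by 2.37 (adjusted p = 0.0181, but 0.0632 without control array 2; 3.05 without control array 4) and Dbp, a clock output gene, by 2.79 (0.0198, but 0.0697 without control array 2 and 0.0541 without C60 array 2). Arrays of the groups overlapped for Dbp, where control array 4 read far above the other 3 (2.30 against at most -0.92), and without it the fold was 3.63. RT1-CE10 was higher by 2.24 (0.0392), with adjusted p between 0.0527 and 0.111 without any 1 array other than C60 array 4 (2.84 without it) and 0.05 without a filter. Of the other 7, Nisch and Tmcc2 were not called without control array 2 (0.056 and 0.0676) or C60 array 3 (0.0509 and 0.0561). Tent5b was not called without control array 2 (0.0716), C60 array 1 (0.0549) or C60 array 3 (0.0564). Ggnbp1 was not called without control array 2 (0.0681), C60 array 2 (0.0664) or C60 array 3 (0.0594). Lemd2 and Pkn3 were not called without control array 2 (0.104 and 0.0823), C60 array 1 (0.0642 and 0.0565), C60 array 2 (0.0687 and 0.0622) or C60 array 3 (0.0716 and 0.0613). Rap1gap had adjusted p between 0.0549 and 0.0983 without any 1 array other than control array 3. With normexp background correction Rap1gap and Ggnbp1 were not called (adjusted p = 0.292 and 0.115).

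The largest falls after C60 at 1 month stayed called whichever array was left out. They included Or8b52, an olfactory receptor gene (at least 4.81-fold lower; adjusted p = 0.000296), Golt1a (at least 5.09-fold), the enamel protein gene Ambn (at least 4.11-fold), the retinal carrier gene Rbp3 (at least 6.3-fold; its other probe gave -0.15) and Aox2 (at least 2.53-fold), none of them well above background on a C60 array. Golt1a and Aox2 were not called with normexp background correction (adjusted p = 0.0529 and 0.125). Smcp fell by 3.58 on the log2 scale (1 of 4 C60 arrays well above background), and Oit3 by 3.28 (3 of 4; 2.67 and 3.93 without control array 2 or 3 and 2.63 without C60 array 2). The 1-month control mean lay at least 1 log2 unit above all other slides for Aox2 and Smcp, and below them for Ube2o, Lemd2, Nisch, Pkn3, Tent5b and Tmcc2 among the rises.

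The median log2 fold of all genes in C60 against control at 1 month was -0.09, and 0.04 with quantile normalization, a shift of 0.12, so medians of lists are relative to all genes. Circadian clock genes were higher for 7 of 14 and lower for 1 (7 and 2 adjusted over the list alone; relative median 0.69), and camera did not call the list (adjusted p = 0.0526, and adjusted p = 0.54 with an estimated correlation). MHC class II genes were higher for 4 of 13 (5 adjusted over the list alone; relative median 0.31), including RT1-DOb (1.05, SE 0.22; adjusted p = 0.00461) and RT1-DMa (0.51). Endothelial markers were higher for 9 of 25 and lower for 1 (9 and 1 adjusted over the list alone; relative median 0.22). Camera gave adjusted p = 0.0444 for both lists, but 0.241 with quantile normalization and 0.0631 without control array 3. Under a filter on every array these were 0.124 and 0.132, and adjusted p = 0.54 with an estimated correlation. In the macrophage activation list 2 of 30 were higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.604). Over all genes limma called 4987, with 1899 higher and 3088 lower, of which 102 and 1666 by at least 1 log2 unit. Quantile normalization called 2444 higher and 1970 lower (55.4 percent higher against 38.1 percent; 448 and 969 by at least 1 log2 unit). The count was 2797 without control array 2, and 2929, 2483 and 3005 without C60 array 1, 2 or 3, and 3126 in a fit of the compared groups only.

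**Figure D2:**
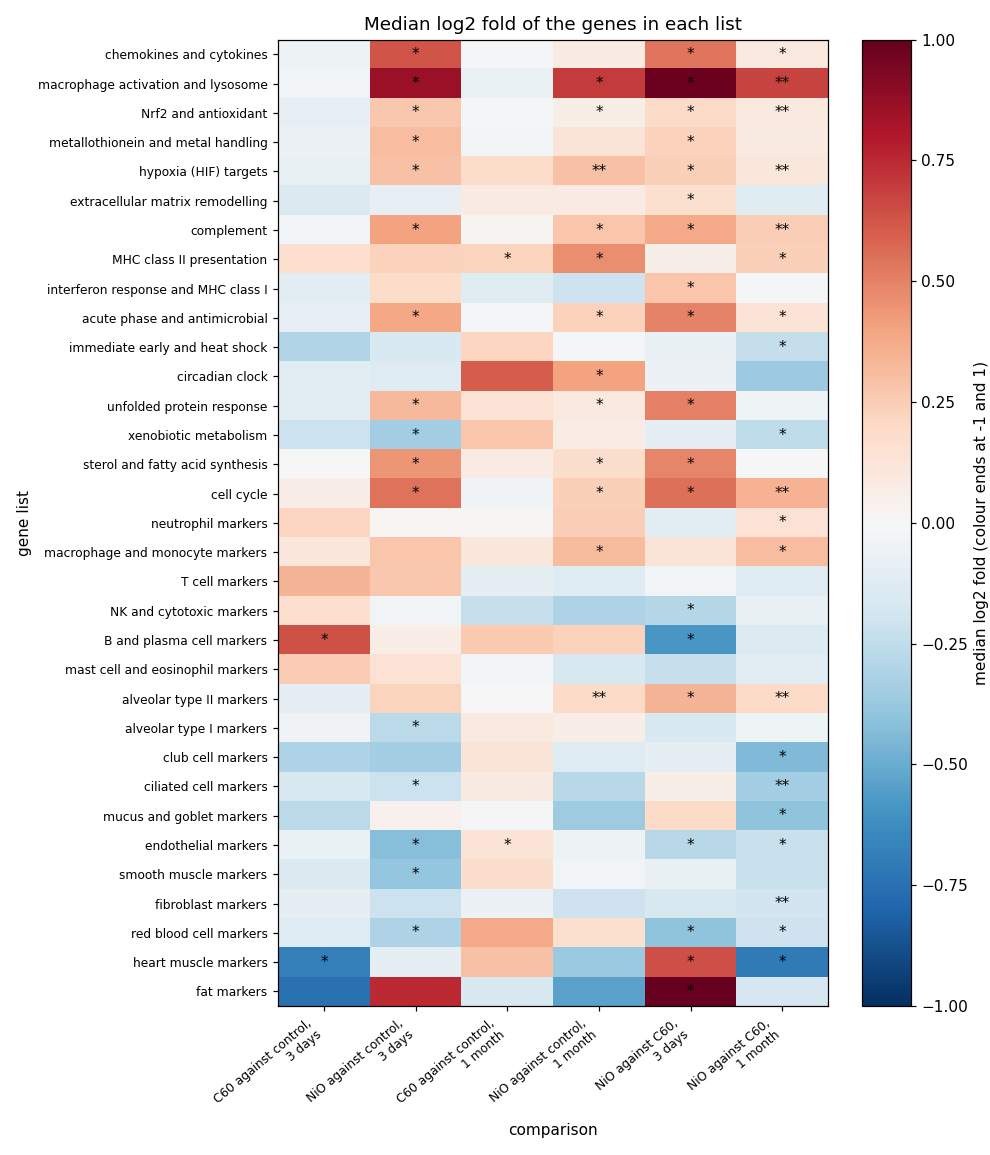
Median log2 fold of 33 gene lists in 6 comparisons, with the colour scale ending at -1 and 1. A star marks a camera adjusted p under 0.05 with the preset correlation and a double star a call that also holds with an estimated correlation. Macrophage activation and lysosome genes were higher in NiO lungs in all 4 comparisons that hold NiO (medians 0.87, 0.70, 0.98 and 0.68) and near 0 in C60 against control (-0.03 and -0.07).

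Compared directly at 3 days, single macrophage and chemokine genes were higher in NiO than in C60 lungs. Mmp12 was higher by a log2 fold of 6.21 (SE 0.69, n = 4 NiO and 2 C60 arrays; adjusted p = 6.39e-05) and Cd177 by 4.50. Rnase9, Dmkn and Mmp7 were at least 11.8, 8.44 and 8.51-fold higher, with no C60 array well above background. Tac1 was at least 20.2-fold lower in NiO lungs (adjusted p = 5.75e-08), Csprs at least 2.63-fold lower (adjusted p = 0.0631 with normexp background correction). Serpinb10, the gluconeogenic enzyme gene Fbp1 and Acot1 differed by -3.64, -2.90 and -2.62. All 10 stayed called whichever array was left out. Macrophage activation genes were higher for 17 of 30 (21 adjusted over the list alone, where 1 was lower; camera adjusted p = 8.1e-12, and adjusted p = 0.0959 with an estimated correlation). Chemokines were higher for 13 of 33, with 1 lower (17 and 2 adjusted over the list alone; camera adjusted p = 4.19e-07, and adjusted p = 0.13 with an estimated correlation), including Ccl22 (2.78, SE 0.17; adjusted p = 5.75e-08), Ccl7 (2.87) and Cxcl2 (2.79). In the metal handling list 3 of 12 were higher (3 adjusted over the list alone; camera adjusted p = 0.0087, but adjusted p = 0.0959 with an estimated correlation, 0.0537 without C60 array 2 and 0.0767 without NiO array 1). The transferrin receptor gene Tfrc was higher by 1.51 (SE 0.15), the metallothionein gene Mt3 at least 1.36-fold (0.0764 without C60 array 1, 0.138 with normexp background correction) and the zinc transporter gene Slc30a4 by 0.71 (0.258 without C60 array 2).

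Markers of neighbouring tissue differed in the same comparison: fat markers were higher in NiO lungs for 5 of 13 (8 adjusted over the list alone; median 1.72; camera adjusted p = 0.00542) and heart muscle markers for 1 of 18 (10 adjusted over the list alone; median 0.65; 0.000316). Without C60 array 2 these were 0.0946 and 0.128, and the fat list was 0.121 without NiO array 1 and 0.199 with all 4 C60 arrays (0.172 with these averaged in pairs). Both had adjusted p = 0.409 with an estimated correlation. Further lists called by camera in this comparison were matrix remodelling, interferon response, acute phase genes, and NK cell, B and plasma cell, alveolar type II and red blood cell markers. Each of them lost its call under some alternative, the interferon list for example without NiO array 1 (camera adjusted p = 0.312). Over all genes 1965 were called between NiO and C60 at 3 days, 1276 higher and 689 lower (64.9 percent higher, against 52 percent with 1068 and 987 after quantile normalization). The count was 587 and 839 without C60 array 1 or 2 and 7152, 1109 and 1149 without NiO array 1, 2 or 3. It was 5960 with all 4 C60 arrays and 747 without NiO arrays 2 and 3 together. A fit of the compared groups only called 62.

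At 1 month macrophage genes were again among the largest rises in NiO against C60 lungs. Mmp12 was higher in NiO lungs by a log2 fold of 3.35 (SE 0.56, n = 4 and 4; adjusted p = 0.00563; 2.50 without NiO array 3), Atp6v0d2 by 3.17, Trem2 by 2.89, Slc26a4 by 2.83 and the secreted phosphoprotein gene Spp1 by 2.55. Tac1 was lower by -6.10 (SE 0.31; adjusted p = 7.16e-09; 1 of 4 NiO arrays well above background), Vsig4 at least 8.37-fold, Fbp1 by -2.85 (SE 0.30; adjusted p = 0.00011) and the kallikrein gene Klk6 by -2.34. Alox15, a lipoxygenase gene, was lower by -2.12 (adjusted p = 0.0421), with 0.11, 0.114 and 0.125 without C60 array 2, 3 or 4. It had 0.142, 0.131 and 0.137 without NiO array 1, 2 or 3, and 0.0851 with quantile normalization. Macrophage activation genes were higher for 13 of 30 (18 adjusted over the list alone, where 2 were lower; median 0.68; camera adjusted p = 8.86e-26, and adjusted p = 0.0132 with an estimated correlation). Ciliated cell markers were lower for 1 of 22 (11 adjusted over the list alone; median -0.34; 9.69e-12, and adjusted p = 0.0149 with an estimated correlation), the member being Dynlrb2 (-0.65; between 0.0575 and 0.124 without any 1 array other than C60 array 1 or NiO array 4, and 0.0559 without a filter). Complement genes were higher for 3 of 23 (4 adjusted over the list alone; 5.81e-09, and adjusted p = 0.0447 with an estimated correlation): C4bpa by 1.23, C5 by 0.94 and the C5a receptor gene C5ar1 by 0.92. These were not the only lists called by camera in this comparison. Others were chemokines, neutrophil markers, mucus and goblet markers, xenobiotic metabolism, immediate early genes and red blood cell markers. Each of them lost its call under some alternative, the chemokine list for example without NiO array 3 (camera adjusted p = 0.513).

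Heart muscle markers were lower in NiO than in C60 lungs at 1 month for 1 of 18 (12 adjusted over the list alone; median -0.71; camera adjusted p = 4.99e-12, and adjusted p = 0.0786 with an estimated correlation). The member was the atrial myosin light chain gene Myl7 (-0.76; between 0.0575 and 0.105 without C60 array 1, 2 or 4 or NiO array 1, 2 or 3). Between NiO and C60 at 1 month 303 genes were called, 192 higher and 111 lower, 67 and 28 of them by at least 1 log2 unit. The count was 154, 160 and 164 without C60 array 1, 2 or 4, and 167, 159 and 140 without NiO array 1, 2 or 3. A fit of the compared groups only called 651.

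The effect of NiO differed between the times for single chemokine and macrophage genes, while neither list as a whole was called. The rise of Cxcl2 was smaller at 1 month than at 3 days by a log2 difference of -3.24 (adjusted p = 0.000305), that of Cxcl1 by -2.70, of Ccl7 by -2.34 and of Mmp12 by -3.21 (adjusted p = 0.009; -4.06 without NiO array 3 of the 1-month slide). Among chemokine genes 14 of 33 had a lower and 2 a higher effect at 1 month (14 and 2 adjusted over the list alone), and among macrophage activation genes 10 of 30 a lower and 4 a higher one (13 and 6 adjusted over the list alone). Camera gave adjusted p = 0.154 and 0.639 for these lists, and over all genes 9376 of 24984 had a different effect. Endothelial markers had a higher effect at 1 month for 8 of 25 and a lower one for 1 (8 and 1 adjusted over the list alone), such as Tie1 (1.75, adjusted p = 0.00389). Large differences upward were those of Rab15 (5.94; 7.35, 5.00 and 5.11 without NiO array 1, 2 or 3 of the 3-day slide, 4.86 and 6.62 without array 2 or 3 of the 1-month controls) and Zbtb16 (4.24). Downward they were Spmip8 (-6.35; -5.70 and -7.04 without these 2 controls), Rnase11 (-5.60 or lower; -4.94 and -6.40), Or13a25 (-2.94 or lower; -2.28 and -3.61, and -2.20 without NiO array 3 of the 3-day slide) and Or8u3 (-3.91 or lower). Rpgrip1 (1.73 or higher; 3.07 and 0.96 without array 1 or 3 of the 3-day controls and 2.41 without array 2 of the 1-month controls) lost its call without any 1 of 10 arrays (adjusted p up to 0.113) and with normexp background correction (0.448). Acsm5 (3.03; 2.24 without array 3 of the 1-month controls) lost it without any 1 of 7 arrays (up to 0.082). Of these 9376 genes, 3613 went upward and 5763 downward. Against this stood 5169 and 3457 with quantile normalization (59.9 percent upward against 38.5 percent), where the median of all genes moved from -0.18 to 0.03, a shift of 0.21. Without NiO arrays 2 and 3 of the 3-day slide 3970 genes were called.

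For C60 the effect differed between the times in 2663 genes, 1175 upward and 1488 downward (44.1 percent upward; 52 percent with quantile normalization, which moved the median of all genes by 0.11, from -0.05 to 0.06). Dsg2 (3.54), Ntm (2.84 or higher), Spry4 (2.35 or higher) and Rnf151 (1.38 or higher; 0.77 without C60 array 2 of the 1-month slide), which were lower than in controls at 3 days, went upward. For each of these the 3-day control mean lay at least 1 log2 unit above all other slides, and for Slc17a1 below them. Downward went Gpr139 (-2.46 or lower), the phosphate transporter gene Slc17a1 (-3.24 or lower; -4.05 and -2.42 without C60 array 1 or 2 of the 3-day slide) and Or10j3b (-2.81 or lower; -4.01 and -1.60 without the same arrays). Zbtb16 (4.68) was 6.32 without array 2 of this slide and lost its call without array 1 (3.04; adjusted p = 0.126). Or8b1b (-4.00 or lower; -5.33 without array 1 and -4.70 without array 1 of the 1-month controls) lost it without array 2 (-2.66 or lower; 0.115). Or1f20d has no bound, as it was not well above background on any C60 array. With normexp background correction Rnf151, Gpr139 and Or8b1b were not called (0.105, 0.0763 and 0.0598). The count was 1458 and 1325 without C60 array 1 or 2 of the 3-day slide, 5678 with all 4 C60 arrays and 1491 with normexp background correction.

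Control lungs themselves differed between the times in 11468 genes, 6853 higher and 4615 lower at 1 month (59.8 percent higher; 49.4 percent, 5400 and 5542, with quantile normalization, which moved the median of all genes from 0.19 to 0.05). Age, slide and scan day differ together in this comparison.

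**Figure D3:**
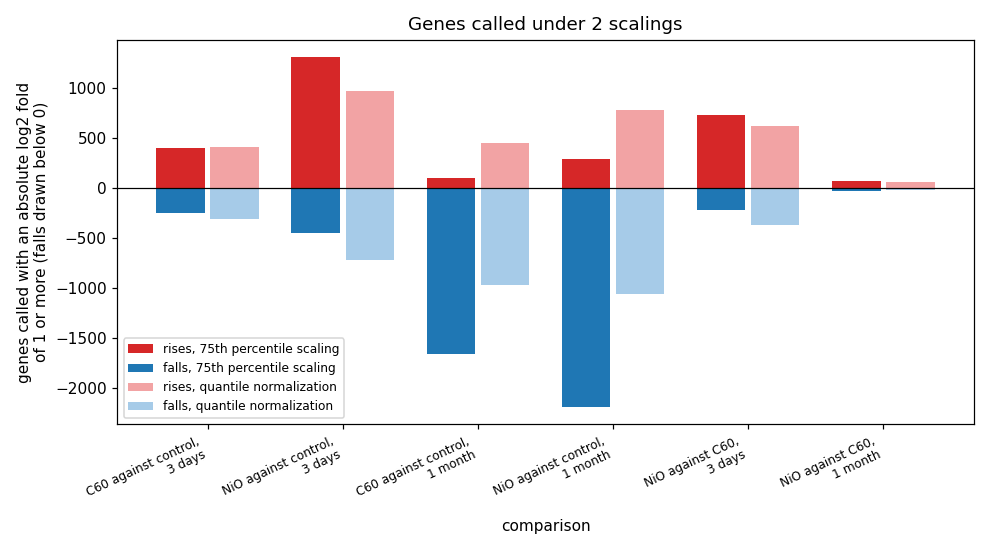
Numbers of genes called with at least 1 log2 unit of change in each comparison, rises above and falls below 0, with scaling to the 75th percentile and with quantile normalization. In NiO against control at 1 month 294 rises and 2191 falls became 778 and 1064 with quantile normalization, and in C60 against control 102 and 1666 became 448 and 969.

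Genes called in C60 against control were often called the same way in NiO against control. At 3 days 448 genes were higher and 284 lower with both particles, where independent lists would share 75.1 and 47, and 10 were called in opposite directions. At 1 month 1391 were higher and 2679 lower with both, against 213 and 613, and 3 went in opposite directions. The log2 folds of both particles, which share their controls, correlated across genes at r = 0.42 at 3 days (0.48 in simulations of unchanged groups) and r = 0.88 at 1 month (0.501 in simulations). Their covariance was 0.14 against a simulated 0.0521 at 3 days and 0.361 against 0.0387 at 1 month, and the simulations shared 0 limma calls. With the 1-month controls split so that each particle had 2 control arrays of its own, r was between 0.5 and 0.806, the covariance between 0.257 and 0.341 and the genes shared in direction between 710 and 1700, with up to 68 in opposite directions. At 3 days the 3 controls cannot be split in this way, and part of the excess may come from the shared controls. The split 1-month controls still lie on 1 slide, so a shift of that slide would move both particles the same way. The simulations held no slide differences. Neither the split nor the simulations can therefore tell shared particle effects from a control slide that stands apart.

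With the slide mean as the unit, limma called 0 genes for NiO and 0 for C60 against control over both times, with 1030 and 698 genes at an unadjusted p under 0.05. With 2 residual degrees of freedom this fit cannot show that changes are absent. Tac1 came closest for NiO (-5.83, SE 0.21; adjusted p = 0.127) and was the 1 gene called by eBayes with a trend (adjusted p = 0.0166). The lowest unadjusted p values for NiO otherwise belonged to Retnla (2.70), Spp1 (2.18) and Gpnmb (1.73) upward and Fbp1 (-2.33) and Angpt4 (-1.98) downward. For C60 they belonged to Retnla (1.52), Nr1d1 (1.86) and Fos (1.35) upward and Angpt4 (-2.08), Hes3 (-1.86) and Ppp1r1c (-2.02) downward, with the smallest adjusted p at 1.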

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

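The splits of the arrays and the test of lower levels in particle-exposed lungs were chosen before their results were seen, and the other tests of explanations in this part only after. After first values had been seen, a bootstrap interval was added to the test of the macrophage share, which moved its verdict from excluded to undecided. Single-array shares were added to the test of lower levels, which left its outcome under the rule as it was. The test of weak signals was moved to the 3-day slides, which chose none of its genes, after a value on 5 slides had been seen, and its verdict stayed too.

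The effect of NiO differed between 1 month and 3 days for 9376 genes by a test of the difference itself, and for 45 genes followed singly (adjusted p between 4.38e-07 and 0.0384). Smaller or lower at 1 month were the inflammatory and macrophage genes Mmp12 (-3.21), Cxcl2 (-3.24), Cxcl1 (-2.70), Ccl7 (-2.34), Cd177 (-2.06), Trem2 (-1.32), Atp6v0d2 (-1.59), Mmp7 (-2.48 or lower), C3 (-0.96), C4bpb (-1.70) and Sod2 (-1.06). The same held for the cell cycle genes Cks2 (-1.45), Ttk (-0.92) and Top2a (-0.88) and the sterol synthesis genes Fdft1 (-1.05), Hmgcs1 (-1.50) and Insig1 (-1.23). It also held for Slc26a4 (-1.77), Rnase9 (-3.68), Spmip8 (-6.35) and Klk1c10 (-3.84), and as bounds for Itih1 (-1.20 or lower), Slc17a1 (-3.75 or lower), Krt73 (-4.52 or lower), Or13a25 (-2.94 or lower) and Smcp (-2.83 or lower). Higher at 1 month were the effects on the endothelial genes Ace (1.01), Eng (1.98) and Tie1 (1.75), on C2 (1.14), RT1-Db1 (0.64) and RT1-DMa (0.62), and on Cebpa (2.30) and Muc1 (0.67). So were those on Meis3 (1.47), Myo7a (1.44), Zbtb16 (4.24), Serpinb10 (1.69), Ctxn1 (2.79), Dsg2 (2.87), Ntm (2.51) and Spry4 (2.84). For Trem2 the NiO mean was 4.61 at 3 days and 4.83 at 1 month, while the control mean went from 1.06 to 2.60. The 3-day control mean lay at least 1 log2 unit beyond all other slides for Ctxn1, Dsg2, Ntm, Spry4, Osbp2, Slc17a1 and Spmip8. The 1-month control mean did so for Krt73, Or13a25, Smcp, Cebpa and Gclm. Gclm, Osbp2 and Sdcbp2 passed the test too, but no size can be given, since a group on the side that leaves it unbounded was not well above background on any array. Calls were lost for C3 without any 1 of 9 arrays (adjusted p up to 0.0771, without NiO array 1 of the 1-month slide), Trem2 without any 1 of 11 (up to 0.0771, without array 1 of the 3-day controls), RT1-Db1 without any 1 of 7 (up to 0.0868, array 3 of these controls) and Muc1 without any 1 of 6 (up to 0.0701, array 1). Klk1c10 lost it without array 3 of these controls (0.0642) or NiO array 3 of the 3-day slide (0.0512), and RT1-DMa without array 2 of these controls (0.0535). Sdcbp2 lost it without array 1 of these controls (0.0865) or NiO array 3 of the 3-day slide (0.0505). It also lost it without NiO array 1 or 2 of the 1-month slide (0.0513 and 0.0528). Without NiO array 3 of the 1-month slide Mmp12 was at -4.06, Cd177 at -2.70, Mmp7 at -3.17 or lower and Rnase9 at -4.43, and Rnase9 was at -3.08 without array 4 and -4.64 without array 2 of the 3-day controls. Without array 2 or 3 of the 1-month controls Spmip8 was at -5.70 and -7.04, Klk1c10 at -3.11 and -4.60, Krt73 at -3.83 and -5.26 or lower and Or13a25 at -2.28 and -3.61 or lower (-2.20 without NiO array 3 of the 3-day slide).

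For C60 the effect differed between the times for 2663 genes, and for 26 genes followed singly (adjusted p between 6.07e-08 and 0.0292). Lower at 1 month were Celsr1 (-3.12), Cldn9 (-2.30), Acot1 (-2.59), Rtn4rl1 (-3.39), Or14a258 (-2.46) and Or5w22 (-2.93), and as bounds F2r (-3.14 or lower), Or9s14 (-2.33 or lower), Prdm1 (-1.31 or lower), Mgat5b (-0.38 or lower), Olr193 (-1.59 or lower) and Or12e9 (-3.33 or lower). Higher were Dsg2 (3.54), Ctxn1 (3.03), F2rl3 (1.83), Csrp3 (1.47), Nos3 (1.64) and Tent5b (2.29), and as bounds Ntm (2.84 or higher), Spry4 (2.35 or higher), Rnf151 (1.38 or higher; 0.77 without C60 array 2 of the 1-month slide) and Ggnbp1 (1.26 or higher). Or8b52, Golt1a, Aox2 and Smcp passed the test with all arrays, but no size can be given, and each lost its call without 1 array. Without C60 array 1 of the 3-day slide calls were lost for F2rl3 (1.49), Ggnbp1, Mgat5b, Tent5b (1.67), Aox2 and Smcp. Without array 2 they were lost for Csrp3 (1.11), Prdm1, Ggnbp1, Mgat5b, Aox2, Golt1a and Or8b52, and Tent5b was at 2.91. Nos3 lost its call without any 1 of 8 arrays (1.57 without this array). Mgat5b also lost it without array 1 or 2 of the 3-day controls (adjusted p = 0.0631 and 0.0642). Golt1a and Smcp lost it without array 3 of these controls (0.0553 and 0.0567). The 3-day control mean lay at least 1 log2 unit below all other slides for Celsr1, Cldn9, Rtn4rl1, Or14a258, Or5w22, Or9s14, Mgat5b, Olr193 and Or12e9. It lay as far above them for Dsg2, Ctxn1, F2rl3, Ntm, Spry4, Rnf151 and Tent5b, so the controls may carry much of these differences. For Dsg2 the control mean went from 0.11 to -4.18, the C60 mean from -4.055 to -4.805.

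Dixon's test on the groups of 4 marked single arrays for some of the genes followed singly, and chance marks about 1 in 20 groups. Array 3 of the 1-month NiO slide read higher than the other 3 for C3 (5.98), Hmox1 (2.57), Itih1 (-1.94), Lcn2 (5.60) and Slc26a4 (4.59), the others lying at most at 4.72, 2.09, -3.27, 4.07 and 3.07. Array 2 of the 1-month controls read lower for Myo7a (-4.48), Pkn3 (-5.32), RT1-DOb (-3.78), Tie1 (-1.63) and Trem2 (1.87), the others lying at least at -3.71, -3.80, -3.23, -0.77 and 2.81. Array 4 of these controls read higher for the clock gene Dbp (2.30, others at most -0.92). Array 1 of the 3-day NiO slide read lower for Akr1b8 (2.46) and C4bpa (3.84), and array 4 of the 1-month NiO slide higher for Or13a25 (-6.79). On the 1-month C60 slide the marked values were Aox2 on array 1 (-7.12), Klk6 on array 2 (-0.044), Rap1gap (-5.02) and the slope of the spike-in controls (0.911) on array 3, and Nos3 (-1.13), Pkn3 (-3.21) and RT1-DOb (-2.85) on array 4.

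Arrays 3 and 4 of the 3-day C60 slide, which entered no comparison above, differed from the 3-day controls in 4335 genes by limma (2347 higher, 1988 lower). Both pairs of C60 arrays called 897 genes against the same 3 controls, which makes part of this overlap, and 868 genes were called between the pairs.

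Whether chance could give the counts was asked of other splits into groups of the same sizes. Each group lies on its own slide, so the splits ask only whether arrays of different slides differ. They cannot tell a particle effect from a slide difference, and 1 of 35 is the lowest share that 35 splits can give. Chance allotment of the arrays was excluded for C60 against control at 1 month (4987 genes; highest other split 4; 1 of 35 splits as large), NiO against control at 1 month (7754; 2; 1 of 35), NiO against C60 at 1 month (303; 0; 1 of 35) and control against control between the times (11468; 7053; 1 of 35). It was excluded for the difference of the NiO effect between times as well (9376; 5569; 1 of 100 drawn). It was not excluded for NiO against control at 3 days, where 2 of 35 splits were as large: the real split called 4790 genes, and the split that put NiO array 1 with the 3 controls called 9923, which points to a structure among the NiO arrays. The split with 7053 genes put array 3 of the 1-month controls with the 3-day controls. The comparisons with the C60 pair were not tested in this way.

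The genes called in C60 against control at 3 days were weighed against the state of the slides. For 84.9 percent of those with a fold of 2 or more the control slide mean lay beyond the other 5 slides (34.2 percent of the other genes), and for 35.7 percent the C60 mean did, so a control slide that stands apart may account for much of the list. Raised background on C60 arrays 1 and 2 was argued against as the whole cause, since 88.5 percent of the rises and 69 percent of the falls had 0.5 or more of their log2 fold on arrays 3 and 4. Because these shares use the controls that chose the genes, genes were also called against 2 controls and read on arrays 3 and 4 against the control left out, which gave 81.1 to 88 percent of the rises and 57.9 to 62.3 percent of the falls. A response of the lung to C60 stays open and was not tested apart from the slide, because slide and group coincide.

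Falls of 2-fold or more outnumbered rises at 1 month by 7.45 for NiO and 16.3 for C60. With quantile normalization these became 1.37 and 2.16, so the shape of the signal distribution on the control arrays may carry the excess, though this scaling would also remove a real change in 1 direction. Of the NiO falls 76.5 percent, and of the rises 18.4 percent, lay in the lowest 33.3 percent of genes by signal on the 3-day slides. Weak signals reading higher on the 1-month control slide would give this. The filter may also give part of it, since it keeps a gene dim on the 3-day slides where it is bright in 1 group at 1 month. The share of falls that entered in this way was not computed. Of 1461 falls shared by both particles, 40.7 percent had a 3-day control mean nearer to the 1-month controls than to the exposed groups (27.9 to 49.2 percent on single arrays). By the rule set beforehand this counted against lower levels in exposed lungs than in any control. The genes were chosen by a high 1-month control mean, though, which by itself draws other controls nearer to the exposed groups. That test therefore cannot decide this explanation. It also rests on the 3-day control slide, which differs in age and scan day, and these stay open.

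Genes that stood apart in NiO lungs from both other groups the same way at both times numbered 103, against 5.51 for independent lists. Slide differences independent at the 2 times were argued against, since 1 gene stood apart in opposite directions (at most 3 under the alternatives other than array weights). With array weights 98 were opposite beside 396 in the same direction, a share between the bounds set for the test, so that setting leaves it open. A larger share of macrophages could not be decided: the macrophage and monocyte markers had a median log2 fold of 0.278 (bootstrap 95 percent interval -0.036 to 0.645, 10000 draws) in NiO against control at 3 days, and that interval holds 0.433, 0.5 of the median of the activation genes. The test was run at 3 days only, while the pattern covers both times. Activation of the macrophages present and a larger number of them therefore cannot be told apart here. The marker interval is wide, and RNA of whole lung gives no count of cells.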

How the results depend on the processing

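Leaving out arrays 2 and 3 of the 3-day NiO slide or arrays 3 and 4 of the 1-month controls, averaging the C60 arrays in pairs, and every alternative for the genes apart from both groups, were chosen after seeing the data. Named genes were run again with 1 array left out, no filter, normexp, quantile normalization and the deposited ratios, lists also with the filter on every array, the other uses of the C60 arrays and an estimated correlation but not with the ratios. In these settings none turned direction, but the 2 probes of Celsr1 did differ in direction. The majority direction of the calls turned with quantile normalization for NiO at 3 days (55.5 to 45.8 percent higher) and at 1 month (36.1 to 55.4), C60 at 1 month (38.1 to 55.4), the NiO and C60 differences between times (38.5 to 59.9 and 44.1 to 52) and the controls (59.8 to 49.4). Of the gene counts under the alternatives 175 stayed within 1.5 times and 50 did not, of the list results 836 kept and 169 lost their call (61 of 71 calls were lost with an estimated correlation) and calls of named genes were lost 116 times and kept 1228 times with 1 array left out, and lost 20 times with normexp, 7 without a filter and 1 with quantile normalization. Against the deposited ratios, which is no test, 108 log2 folds of named genes stayed within 1 SD and 11 did not. Counts that moved were, with array weights, 3401 for C60 and 10757 for NiO against control at 3 days, 9391 and 12972 at 1 month, 8515 and 3135 for NiO against C60, 14214 and 7074 for the differences between times, and 396 for the genes apart in NiO (98 more in opposite directions). With all 4 C60 arrays they were 3025, 5960 for NiO against C60 and 5678 for the C60 difference between times. Normexp gave 3148 for NiO at 3 days, 1088 for NiO against C60 and 1491 for the C60 difference. Fits of the compared groups only gave 826 for NiO at 3 days, 3126 for C60 at 1 month and 62 and 651 for NiO against C60 at the 2 times. The filter on every array gave 1265 for NiO against C60 at 3 days and no filter 196 at 1 month. Without NiO arrays 2 and 3 the counts were 1638, 747 and 3970 for the difference between times. The slide fit with a trend called 1 gene for NiO (0 by limma without it, 1030 at an unadjusted p under 0.05). Fits on fewer groups or arrays have fewer degrees of freedom, which cannot account for counts that rose, such as 651 for NiO against C60 at 1 month. The fit over all groups also shares 1 estimate of the spread. The median SD of a gene was 0.317 in NiO at 3 days, but 0.155 in C60 and 0.136 in NiO at 1 month. The causes of the moved counts were not tested. With 1 array left out the counts ranged from 747 to 916 for C60 and 2265 to 9606 for NiO at 3 days, 2483 to 5151 and 5241 to 7681 at 1 month, 587 to 7152 and 140 to 340 for NiO against C60, 7171 to 13060 and 1325 to 3251 for the differences, 9156 to 11386 for the controls and 64 to 165 for the genes apart in NiO. Where this left 1 C60 array, it was assumed to vary like the other groups. The C60 arrays did not form pairs by the rule set beforehand (arrays 1 and 2 correlated at 0.985). Averaged as 1 with 2 and 3 with 4 they gave 1445 genes for C60 at 3 days, and every count stayed within 1.5 times.

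Array numbers were read from the names of the scanner files and mark the place on the slide. As a replicate block they gave 1167, 4845, 4776 and 7609 genes for C60 and NiO against control at 3 days and at 1 month, 1570 and 281 for NiO against C60, 9173 and 2502 for the differences and 11104 for the controls, each within 1.5 times. Arrays with the same number did not deviate together: correlations of their deviations from the group means were between -0.113 and 0.148 in the particle comparisons, computed after the block counts had been seen.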

Other observations

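The set described here, the genes apart from both other groups, was chosen after seeing the data, as were its tests. Fisher's test takes genes as independent, so its p values are too small for genes that move together. With an estimated correlation camera called neither the macrophage activation nor the Nrf2 list in NiO against control at either time. It did call the macrophage activation list in NiO against C60 at 1 month. In NiO lungs 90 genes were higher and 13 lower than in both control and C60 lungs at both times by limma. The count was 165 without NiO array 1 of the 3-day slide, 68 and 64 without C60 arrays 1 and 2 of the 1-month slide and 67 without NiO array 3 of the 1-month slide. Macrophage activation genes were the main group, with 10 of 30 measured members (Fisher adjusted p = 1.3e-12): Mmp12, Trem2, Atp6v0d2, the lectin gene Lgals3, the lysosomal protease gene Ctsd, the fatty acid carrier gene Fabp5, Chi3l1, and Spp1 (log2 folds against control 2.31 at 3 days and 2.05 at 1 month), Gpnmb (1.96 at 3 days) and Arg1, an arginine-degrading enzyme gene (2.56 and 0.99). Of the Nrf2 and antioxidant list 3 of 31 belonged to it (adjusted p = 0.0393): Hmox1, Akr1b8 and the ferritin light chain gene Ftl1. Others were the growth factor gene Igf1 (0.85 and 1.17), the cholesterol exporter gene Abcg1 (0.61 and 1.13) and the siderophore-binding protein gene Lcn2 (3.26 and 2.21). Among the 13 lower were Tac1, Vsig4, Fbp1 (-2.53 and -2.13), Serpinb10, Csprs and the calcitonin receptor partner gene Ramp3 (-1.06 and -0.66).

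For C60 the same rule gave 1 gene, Mbtps2, a protease gene of sterol regulation (-1.17 and -0.70), where 0.227 was the value for independent lists. With all arrays 330 genes were apart at 3 days and 34 at 1 month before they were joined. In 14 of 32 other settings limma left no gene, among them quantile normalization, normexp, both other filters and both other uses of the C60 arrays. With array weights 6 genes were higher and 7 lower at both times, and 8 stood apart in opposite directions. The control groups stood apart the same way at both times for 47 genes and in opposite directions for 167.

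Genes whose slide mean lay at least 1 log2 unit above or below those of all other slides numbered 339 for the 3-day controls, 106 for C60 and 554 for NiO at 3 days, and 378, 33 and 23 in the same order at 1 month.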
